A study of Danio rerio with 11 samples.

How the data were processed

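RNA was measured in whole brains of adult zebrafish, labelled as about 8 months old, of a TLF x AB background carrying the mpeg1-GFP transgene, which marks macrophages and microglia. The 11 libraries form 4 groups by genotype: 2 control (wild type) libraries, 3 csf1ra-/- libraries, 3 csf1ra-/-;b+/- libraries and 3 csf1ra-/-;b-/- libraries. They are called control, single mutant, csf1rb-heterozygous mutant and double mutant brains from here on. csf1ra and csf1rb are the zebrafish copies of the receptor for colony-stimulating factor 1. The study design speaks of triplicate controls, while the series holds 2 control libraries, and its records do not say whether another was made. Per the labels' protocols, dissected brains were kept on ice in trypsin and snap-frozen, RNA was extracted with Trizol, cDNA was pre-amplified and cut with Tn5 transposase, and single-end reads of 50 nucleotides were sequenced on a HiSeq2500.

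Per the submitters' processing notes, HISAT2, edgeR and the genome build GRCz10 were used. Their versions, the gene counter, its treatment of shared reads and strand, and the annotation release are not given in the sources used here. The deposited signal is a table of CPM (reads per 1e6 reads of a library) for 16536 genes, which the authors scaled per library by a normalization factor, per the file headers and the values themselves. All values were whole multiples of the smallest value above 0 in their column, within a tolerance of 0.001 reads, so the reads behind each value could be recovered. They came to 12.8 to 15.3 M reads per library. Factors recomputed with edgeR's TMM method from the recovered reads equalled the authors' scaling factors, from 0.963 to 1.04. The authors' log2 values, deposited beside the CPM, equalled log2 of the CPM plus about 0.14 and were not used further. The deposited log2 fold changes and adjusted p-values of the authors' own 6 comparisons were used only for comparison with the calls and fold changes computed here. Each listed gene exceeded 1 CPM in at least 3 libraries, so the table had been filtered before deposit, and filters on low values removed 0 genes. Gene symbols are those of the table. It shows 7 IDs without a symbol and 96 symbols shared by more than 1 ID.

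Each of the 6 pairs of genotypes was compared gene by gene with limma's moderated test with a mean-variance trend, on log2(CPM + 1), in 1 fit of all 4 groups without a block, with Benjamini-Hochberg adjustment over 16536 genes. Genes with an adjusted p under 0.05 were called. A quasi-likelihood test on counts had been planned for a table of counts. Because the deposited values are scaled CPM, the test planned for such values was used instead, and edgeR's quasi-likelihood test on the recovered reads became an alternative. Fold changes on the log2(CPM + 1) scale understate those of genes with few reads. All adjusted p-values of single genes are from limma unless another tool is named. The labels do not say that replicates are separate fish, so p-values measure only the spread between these samples, which may be technical. At these depths 1 CPM stands for 12.3 to 15.7 reads. Counting intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

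The genes named were chosen by a rule. csf1ra, csf1rb, their ligands csf1a, csf1b and il34, and cux1a and cux1b were always taken. For each mutant against control, the rule added the 8 called genes with the largest rise and the 8 with the largest fall, and for mutants against each other 5 and 5, among genes with a mean log2 CPM of at least 1 and no overlap between the values of the groups. Of each gene list with a called member, it took up to 4 members with the smallest adjusted p. csf1b is not among the listed genes. Named outside the rule, after their values were seen, were c1qa, c1qb, apoeb, mpeg1.1, hexb, itgae.1, tfr1b and the microglia genes listed as not called in double mutants. There were 34 gene lists for cell types and pathways of the brain. Of their 629 symbols, 504 matched the table. Each list was tested against all other genes with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the 34 lists. The counts "adjusted over the list alone" repeat the adjustment within a list. The groups, tests, gene lists, rule for named genes and the other settings named below, unless stated, were chosen before the data were examined. RefSeq's annotation of GRCz12tu, another build than that of the reads, was used only for which genes share a chromosome or neighbour each other. Calls on the chromosomes of csf1ra and csf1rb were compared with those elsewhere by Fisher's exact test, two-sided, adjusted over chromosomes.

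Replicate numbers are shared between groups in the labels. Those given here are of the titles. Control replicate 2 bears the number 3 in its sample description, where no control bears the number 2, so blocks by title and by description place it with different mutant libraries. In single and csf1rb-heterozygous mutants, libraries with the same number deviated together from their group means, with correlations over genes of 0.368, 0.636 and 0.313. All were above 0.1, so the numbers were taken to pair these libraries. This pairing comes from the data and not from the labels. In the other comparisons at least 1 pair lay at or below 0.0831. No libraries of a group were near-copies of each other, with chi-square values per degree of freedom of 12.5 to 41.4. The fits were tested on simulated counts with 200 changed genes among 16536. For double mutants against control, limma recovered 60.0% of 2-fold and 92.8% of 4-fold changes with 5.91% false calls. For double against single mutants these were 64.4%, 94.6% and 5.02%. A simulated lowering of the microglia list ranked 1 of 34 lists in camera, with 0 other lists called. The simulated genes varied independently of each other. They therefore cannot show how often camera falsely calls lists of genes that vary together.

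Results were also computed with median-of-ratios scaling, DESeq2's Wald test and limma-voom on the recovered reads, pseudocounts of 0.25 and 4, fits of only the groups compared, the replicate number as a block, an estimated correlation, filters on low values, a log2 fold threshold of 1, and leaving out each library in turn. With 1 control library left out, the lone control was assumed to vary like the other groups. edgeR's quasi-likelihood test, a block by the number in the sample description, a minimum mean log2 CPM of 1, fits without the mutant libraries numbered 2, the microglia list without csf1ra and csf1rb, and the chromosome test without the microglia list were added after seeing the data. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.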

Results

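Brain RNA of 11 adult zebrafish libraries was compared between 4 genotypes: 2 control, 3 csf1ra-/- (single mutant), 3 csf1ra-/-;b+/- (csf1rb-heterozygous mutant) and 3 csf1ra-/-;b-/- (double mutant) libraries. The control libraries held 15.3 and 13.3 M reads, the single mutants 12.8, 13.8 and 13.7 M, the csf1rb-heterozygous mutants 14.03, 14.5 and 15.1 M, and the double mutants 15.2, 14.1 and 14.6 M. The 10 most abundant genes took 8.05% to 13.4% of each library. Levels are given as CPM with SD over the libraries of a group (n = 2 for control and n = 3 for each mutant). Reads of 50 nucleotides can be shared between close gene copies, so levels of mhc2dab, cd74a, cd74b, hbaa1, hbaa2, gstm.2, dpyda.3 and clone-named genes are uncertain.

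The receptor genes were lowest in the brains in which both receptors were mutated. csf1ra (ENSDARG00000102986), which controls microglia and pigment cells, stood at 9.66 and 7.33 CPM in the control libraries, at 1.62, 0.952 and 5.10 in single mutants, at 0.905, 0.976 and 0.584 in csf1rb-heterozygous mutants, and at 0.127, 0 and 0.602 in double mutants. csf1rb (ENSDARG00000053624), its paralog, stood at 21.6 and 13.6 CPM in control, 14.4, 8.42 and 10.7 in single mutants, 3.83, 1.60 and 3.63 in csf1rb-heterozygous mutants and 1.97, 2.52 and 2.08 in double mutants. Against control, csf1ra fell by 2.38 log2 units in csf1rb-heterozygous mutants (SE 0.407, adjusted p = 0.0283) and by 2.95 in double mutants (SE 0.407, adjusted p = 0.00555). In single mutants its log2 difference of -1.58 (SE 0.407) did not pass the test (adjusted p = 0.147). csf1rb fell by 2.23 in csf1rb-heterozygous mutants (SE 0.304, adjusted p = 0.00901) and by 2.52 in double mutants (SE 0.304, adjusted p = 0.00277), while its difference of -0.60 in single mutants (SE 0.304) did not pass (adjusted p = 0.482). Between mutants, csf1rb was lower in csf1rb-heterozygous (-1.62, SE 0.272, adjusted p = 0.0439) and in double mutants (-1.91, SE 0.272, adjusted p = 0.00661) than in single mutants. It did not differ detectably between csf1rb-heterozygous and double mutants (-0.29, SE 0.272, adjusted p = 1). csf1ra passed in none of these 3 comparisons between mutants (-0.80, -1.37 and -0.57, with adjusted p = 0.794, 0.127 and 1).

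Some receptor calls were lost with a library left out. Without control replicate 1, adjusted p for csf1ra rose to 0.136 in csf1rb-heterozygous and 0.0609 in double mutants, and for csf1rb to 0.0722 in csf1rb-heterozygous mutants. For csf1ra in csf1rb-heterozygous mutants, 0 of 5 fits with a library left out kept the call. The csf1rb difference between csf1rb-heterozygous and single mutants was likewise called in 0 of 6 such fits, with an adjusted p of 0.192 without single mutant replicate 1. The ligand genes csf1a (4.25 ± 0.223 CPM in control and 3.38 ± 0.472 in double mutants) and il34 (3.16 ± 0.546 and 3.35 ± 0.614), and the neuronal transcription factors cux1a (86.1 ± 4.97 and 84.1 ± 5.03) and cux1b (26.2 ± 2.76 and 26.6 ± 1.45), changed in none of the 6 comparisons, with adjusted p from 0.564 to 1. The labels do not say what the mutations do to the RNA, and both receptor genes are on the microglia and macrophage list below.

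**Figure D1:**
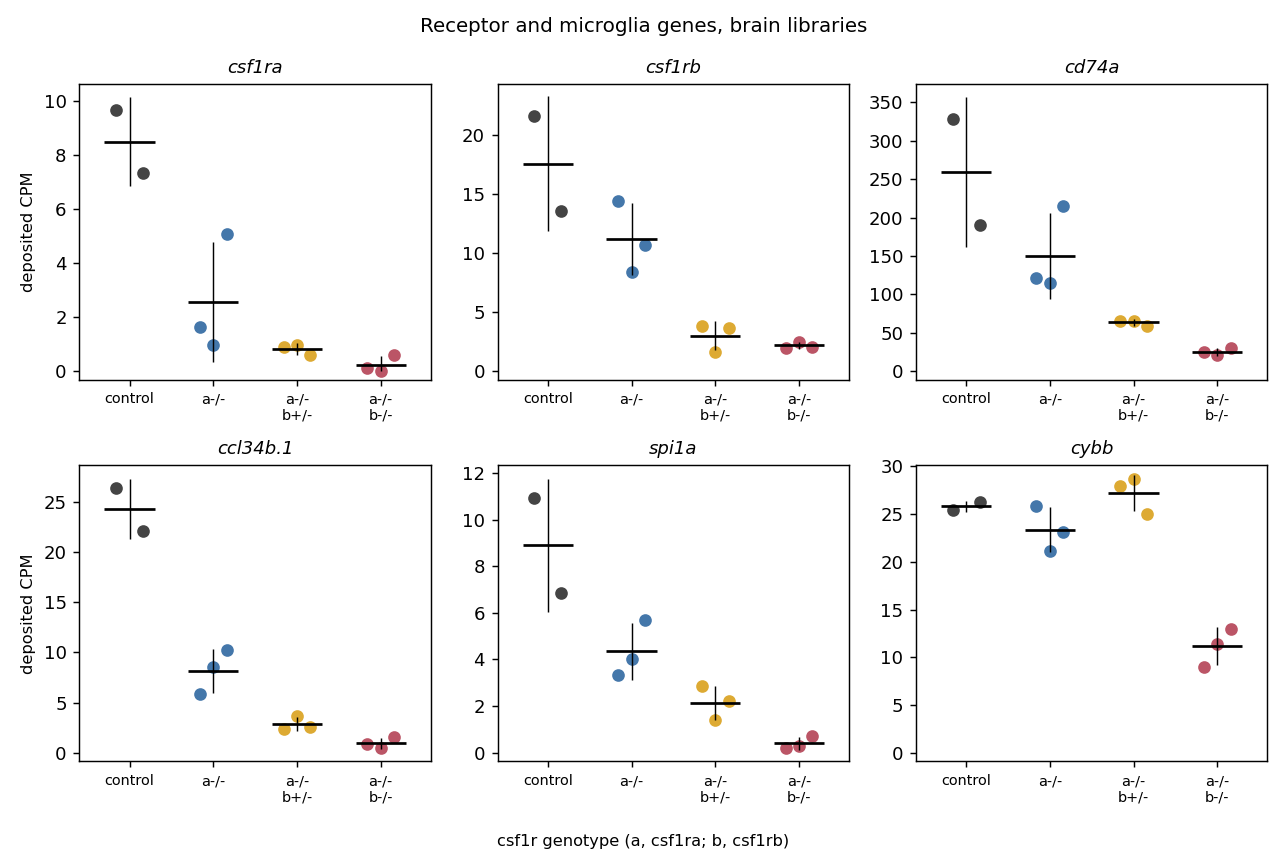
Level of csf1ra and csf1rb in each library (y axis, CPM), by genotype (x axis), with the mean and SD of each group. csf1rb lies at 13.6 CPM or above in both control libraries and at 3.83 CPM or below in all 6 libraries with a csf1rb mutation.

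The comparison of single mutants with control asks how the transcriptome of brains with csf1ra alone mutated differs. Genes of microglia and macrophages had a median log2 fold change of -0.68 (a ratio of 0.624, and -0.29 and -1.14 on the log2 scale without control replicates 1 and 2), with 32 of 33 members below 0 (camera, adjusted p = 7.75e-13, and adjusted p = 0.645 with an estimated correlation). Set against the mean of the controls, the list median was -0.41 in single mutant replicate 3 and -0.43 in control replicate 2. Only ccl34b.1, a chemokine gene, passed the test on its own, falling from 24.3 ± 3.03 to 8.18 ± 2.19 CPM (-1.49, adjusted p = 0.0476). Adjusted over the list alone, 11 members fell and 1 rose. Genes of cholesterol synthesis had a median of 0.47 (23 members, adjusted p = 1.58e-12, and adjusted p = 0.131 with an estimated correlation). lss (lanosterol synthase, 7.56 ± 0.654 to 18.4 ± 2.08 CPM), fdft1 (squalene synthase, 6.13 ± 0.261 to 14.1 ± 1.90) and hmgcs1 (HMG-CoA synthase, 44.4 ± 0.347 to 99.2 ± 13.1) rose by 1.17, 1.08 and 1.14 log2 units (adjusted p = 0.00741, 0.0202 and 0.0269), and 11 members rose and 1 fell adjusted over the list alone.

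Camera with the preset correlation called 7 of the 34 lists in single mutants, and 0 with an estimated correlation, where the lowest adjusted p was 0.131. All 9 erythrocyte genes, such as the globins, were higher, with a median of 1.31 and 0 of them called over all genes but 9 adjusted over the list alone (adjusted p = 6.75e-10, and adjusted p = 0.196 with an estimated correlation). Immediate early genes, which respond within minutes to neuronal activity or stress, had a median of 0.67 (22 members, 0 called and 4 risen adjusted over the list alone, adjusted p = 5.79e-08, and adjusted p = 0.571 with an estimated correlation). Genes of the cytosolic ribosome had a median of 0.21 (25 members, 0 called either way, adjusted p = 1.59e-05, and adjusted p = 0.645 with an estimated correlation). Interferon response genes had a median of -0.77 (14 members, 0 called and 1 fallen adjusted over the list alone, adjusted p = 2.92e-05), and pan-neuronal and synaptic genes one of -0.10 (23 members, 0 called and 1 fallen adjusted over the list alone, adjusted p = 0.0104). Both had an adjusted p of 0.645 with an estimated correlation. Without control replicate 1, the interferon median was -0.31 (adjusted p = 0.245). The neuronal call was lost without control replicate 2 (adjusted p = 0.664) or single mutant replicate 3 (adjusted p = 0.0868). Of the 22 immediate early genes, 10 differed between the replicate numbers in the sample descriptions (p = 9.95e-07, Fisher's exact test), where no control library is numbered 2. The 3 mutant libraries numbered 2 lay at 19.1 to 39.7 on the first principal component (26.9% of the variance), and the other 8 libraries at -30.9 to 6.87.

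Leaving out 1 library brought calls for other lists in single mutants. Antigen presentation, at -0.17 with all libraries (adjusted p = 0.089), had a median of -0.54 without control replicate 2 (adjusted p = 9.29e-07) and of -0.21 without single mutant replicate 3 (adjusted p = 0.00802). Without control replicate 2, hypothalamic neuropeptides (0.26, adjusted p = 0.00148) and oligodendrocytes and myelin (-0.22, adjusted p = 0.0343) were called as well. With control replicate 1 left out, radial glia (-0.22, adjusted p = 0.000123), heat shock (-0.21, adjusted p = 0.0153), excitatory neurons (-0.23, adjusted p = 0.0163), lysosome (0.11, adjusted p = 0.0349) and inhibitory neurons (-0.17, adjusted p = 0.0473) were. Single mutant replicate 1 left out brought radial glia (-0.27, adjusted p = 0.0028), excitatory neurons (-0.21, adjusted p = 0.0408) and upper layer homologs (-0.22, adjusted p = 0.0465), and replicate 2 left out brought retina and pineal (-0.99, adjusted p = 0.00045), heat shock (-0.17, adjusted p = 0.00733) and the circadian clock (0.15, adjusted p = 0.0288).

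In single mutants 49 genes rose and 29 fell of 16536, and 67 of these 78 changed by at least 1 log2 unit. Among genes with a mean log2 CPM of at least 1 and no overlap between the groups, as in each such ranking below, the largest rises were mostly in clone-named genes: BX901918.1 (1.43 ± 0.814 to 37.3 ± 16.2 CPM, 3.93), si:dkey-61p9.9 (3.56), si:dkey-159n16.2 (3.37), si:dkey-222p3.1 (2.91), si:dkey-207m2.4 (2.60), si:ch211-209j12.1 (2.13) and CT025651.1 (2.07), with adjusted p from 0.000236 to 0.0319. cep152, which encodes a centrosome protein, rose from 1.13 ± 0.174 to 7.67 ± 1.01 CPM (2.02, adjusted p = 0.0101). The largest falls among them were in si:ch211-181d7.3 (119 ± 17.6 to 6.19 ± 3.00 CPM, -4.15), BX322555.3 (-3.49), si:ch211-272b8.6 (-2.82) and AL928808.1, with 137 reads in control and 1 in single mutants (a ratio of 193 in CPM, 95% counting interval 34.1 to 7680). Also lower were c3b.2, a complement C3 gene (8.55 ± 3.25 to 0.907 ± 0.697 CPM, -2.35, adjusted p = 0.028), MFN1, which encodes a protein of mitochondrial fusion (8.09 ± 0.641 to 1.52 ± 0.616, -1.88, adjusted p = 0.0128), paqr3b (9.11 ± 2.08 to 1.92 ± 1.12, -1.86, adjusted p = 0.0307) and dpyda.3, of the pyrimidine-degrading enzyme family (15.8 ± 4.5 to 3.91 ± 0.606, -1.76, adjusted p = 0.00741). By the rule that chose these 16 genes, all 3 mutant libraries lay outside the control range for each of them. Of the 20 named calls, 9 held in all 5 fits with a library left out, all of them clone-named genes. ccl34b.1, hmgcs1 and si:dkey-222p3.1 were called in 0 of these 5 fits. With control replicate 1 left out, adjusted p was 0.196 for ccl34b.1, 0.0633 for lss, and 0.171 for both c3b.2 and paqr3b. Without control replicate 2 it was 0.0651 for CT025651.1, 0.0973 for cep152, 0.0884 for MFN1, 0.0901 for dpyda.3, 0.299 for si:dkey-222p3.1, 0.154 for fdft1 and 0.17 for hmgcs1. The count of 78 fell to 29 without control replicate 2, to 36 without single mutant replicate 2 and to 49 without single mutant replicate 3. Rises and falls numbered 47 and 12 without control replicate 1 and 14 and 15 without control replicate 2, so the excess of rises depended on a control library.

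The comparison of csf1rb-heterozygous mutants with control asks how brains with 1 mutated csf1rb copy besides csf1ra differ. The microglia and macrophage list had a median of -1.51 (a ratio of 0.35, and -1 on the log2 scale without control replicate 1), with 31 of 33 members below 0 and 14 of them fallen (adjusted p = 5.91e-27, and adjusted p = 0.5 with an estimated correlation). ccl34b.1 fell from 24.3 ± 3.03 to 2.89 ± 0.711 CPM (-2.71, SE 0.28, adjusted p = 0.00203), lgals9l1, a galectin gene, from 45.2 ± 33.3 to 1.73 ± 0.268 (-3.87, SE 0.446, adjusted p = 0.00342) and cd74a, the invariant chain of MHC class II, from 259.6 ± 98.1 to 63.5 ± 4.07 (-1.96, SE 0.278, adjusted p = 0.011). The complement genes c1qa (-2.04, adjusted p = 0.0436) and c1qb (-1.95, adjusted p = 0.0315) and the apolipoprotein gene apoeb (-0.86, adjusted p = 0.024), chosen after their values were seen, also fell, but each was called in only 1 of 5 fits with a library left out (adjusted p = 0.17 and 0.114 without control replicate 1 for c1qa and c1qb, and 0.131 without control replicate 2 for apoeb). Adjusted over the list alone, 27 members fell and 1 rose. gh1 (ENSDARG00000038185), growth hormone of the pituitary, fell too: 94.3 ± 12.8 CPM in control against 2.39 ± 4.14, with 2 of the 3 mutant libraries at 0 (-5.56, SE 0.715, adjusted p = 0.00705).

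Antigen presentation and interferon genes were lower in csf1rb-heterozygous mutants. Of 13 antigen presentation genes (median -0.58), cd74a and mhc2dab fell, and 5 fell adjusted over the list alone (adjusted p = 9.09e-07, and adjusted p = 0.5 with an estimated correlation). cd74a and cd74b are on the microglia and macrophage list too, so these 2 lists are not independent. mhc2dab, a class II chain, had 622 reads in control and 3 in the mutants, a CPM ratio of 325 (95% counting interval 111 to 1580). Double mutants held 65 reads (21.4 times that CPM, 7.02 to 107), so mhc2dab was not lowest there. Of 14 interferon response genes (median -1.47), 0 were called over all genes and 8 fell adjusted over the list alone (adjusted p = 3.17e-08, and adjusted p = 0.5 with an estimated correlation). grna (granulin, -1.87, adjusted p = 0.0485) of the lysosome list, which is on the microglia list as well, and vamp2 (synaptobrevin, 192.5 ± 9.07 to 121.9 ± 14.6 CPM, -0.66, adjusted p = 0.021) of the pan-neuronal list were the only members of those lists to pass, and neither list was called (adjusted p = 0.425 and 0.143). The pan-neuronal list was called without control replicate 1 (adjusted p = 0.0025) or csf1rb-heterozygous replicate 2 (adjusted p = 0.0401). Pituitary hormones were also called without control replicate 1 (adjusted p = 0.0462), and hypothalamic neuropeptides (adjusted p = 0.0058), proliferation (0.0139) and erythrocytes (0.0156) without control replicate 2.

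Camera called 12 of the 34 lists in csf1rb-heterozygous mutants with the preset correlation and 0 with an estimated one, the microglia and macrophage list among them. Beyond those above, lower medians were called for radial glia (-0.35, adjusted p = 0.000293), excitatory neurons (-0.18, adjusted p = 0.0286), upper layer cortical homologs (-0.16, adjusted p = 0.0324), epidermis and muscle (-0.88, adjusted p = 0.0216) and heat shock and unfolded protein response (-0.21, adjusted p = 0.0244). Higher medians were called for immediate early genes (0.44, adjusted p = 0.00156) and cholesterol synthesis (0.24, adjusted p = 0.0109). All 7 had adjusted p = 0.5 with an estimated correlation. Retina and pineal genes were lower (-0.99, adjusted p = 0.0109) and ribosome genes higher (0.13, adjusted p = 0.0109), both with adjusted p = 0.803 with an estimated correlation. In these 9 lists 0 members were called over all genes, while 3 radial glia genes fell and 1 immediate early gene rose adjusted over the list alone. Immediate early genes differed by replicate number too, as given above. Without control replicate 2, adjusted p rose to 0.123 for radial glia, 0.4 for excitatory neurons, 0.211 for upper layer homologs and 0.301 for heat shock, and the epidermis and muscle median turned to 0.22 (adjusted p = 0.343). Without control replicate 1, it rose to 0.0736 for retina and pineal, 0.284 for cholesterol synthesis and 0.0741 for the ribosome. Without csf1rb-heterozygous replicate 1 it was 0.127 for epidermis and muscle, 0.0531 for heat shock and 0.0507 for upper layer homologs. Leaving out replicate 2 of that group gave the ribosome a median of 0.03 (adjusted p = 0.54) and excitatory neurons one of -0.105 (adjusted p = 0.0627). Leaving out its replicate 3 gave retina and pineal a median of -0.285 (adjusted p = 0.218), while heat shock and upper layer homologs lost their calls (adjusted p = 0.196 and 0.0669) at medians of -0.20 and -0.16.

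In csf1rb-heterozygous mutants 44 genes rose and 67 fell, 91 of them by at least 1 log2 unit. Large falls included tgm2l, a transglutaminase gene (15.7 ± 8.11 to 1.41 ± 0.289 CPM, -2.71, adjusted p = 0.00329), mrc1b, a mannose receptor gene (18.5 ± 10.5 to 1.76 ± 0.921, -2.77, adjusted p = 0.0259), lgals3bpb, a galectin-binding protein gene (87.7 ± 77.0 to 6.07 ± 1.08, -3.32, adjusted p = 0.0314) and si:dkey-71b5.3 (-3.27, adjusted p = 0.0259). The largest rises were in BX901918.1 (3.92), si:dkey-159n16.2 (3.02), si:ch211-209j12.1 (2.78), fam189a2 (6.59 ± 0.259 to 45.1 ± 11.8 CPM, 2.57), CT025651.1 (2.45), the centriole gene cep135 (12.99 ± 3.2 to 70.4 ± 20.4, 2.33), CU856518.1 (2.33) and chrne, a subunit of the acetylcholine receptor (0.587 ± 0.285 to 6.67 ± 2.99, 2.22), with adjusted p from 0.000914 to 0.0489. Of the 21 named calls, 8 held in all 5 fits with a library left out, among them gh1, mhc2dab, lgals9l1, ccl34b.1 and tgm2l. Without control replicate 1, adjusted p was 0.0789 for cd74a, 0.224 for grna, and 0.146 for both lgals3bpb and mrc1b. With control replicate 2 left out, it was 0.139 for vamp2, 0.231 for fam189a2, 0.155 for cep135, 0.277 for chrne, 0.112 for CU856518.1, 0.141 for si:dkey-71b5.3 and 0.0569 for si:dkey-159n16.2. The count of 111 was 62 and 61 without control replicates 1 and 2, and 56, 53 and 48 without the mutant replicates 1 to 3. Rises and falls numbered 38 and 24 without control replicate 1 and 12 and 49 without control replicate 2, so the excess of falls depended on a control library. Members of the microglia list that fell numbered 2 without control replicate 1 and 6, 6 and 5 without each mutant.

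The comparison of double mutants with control asks how brains with both receptor genes mutated differ. Microglia and macrophage genes had a median of -2.28 (a ratio of 0.207, and -1.63 on the log2 scale without control replicate 1), with 32 of 33 members below 0 and 26 of them fallen (adjusted p = 3.32e-43, and adjusted p = 0.268 with an estimated correlation). ccl34b.1 fell from 24.3 ± 3.03 to 0.932 ± 0.562 CPM (-3.75, SE 0.28, adjusted p = 0.000202), cd74a from 259.6 ± 98.1 to 25.2 ± 5.06 (-3.28, SE 0.278, adjusted p = 0.000538), lgals9l1 from 45.2 ± 33.3 to 1.41 ± 1.16 (-4.14, SE 0.446, adjusted p = 0.00161) and spi1a, a myeloid transcription factor gene, from 8.89 ± 2.86 to 0.405 ± 0.291 (-2.80, SE 0.292, adjusted p = 0.00161). Chosen after their values were seen, mpeg1.1 and hexb stand here too. mpeg1.1, whose promoter drives the transgene of this line, fell from 16.7 ± 2.58 to 2.56 ± 2.16 (-2.47, adjusted p = 0.0236) but was called in only 1 of 5 fits with a library left out (adjusted p = 0.149 without control replicate 1). hexb, a lysosomal enzyme gene often used as a microglial marker, was not called in any mutant, at 41.7 CPM in control and 56.4, 51.9 and 49.3 in single, csf1rb-heterozygous and double mutants.

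Of the microglia list, 32 members fell in double mutants adjusted over the list alone. Set against the mean of the controls, the median of the list was 0.43 and -0.43 in the control libraries themselves, -0.78, -0.97 and -0.41 in single, -1.27, -1.58 and -1.59 in csf1rb-heterozygous, and -2.32, -2.44 and -2.01 in double mutant libraries. The 7 members not called in double mutants were hexb, apoeb, c1qc, rac2, hcls1, laptm5 and si:ch211-212k18.7. Members that fell numbered 11 without control replicate 1 and 16 without double mutant replicate 1.

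**Figure D2:**
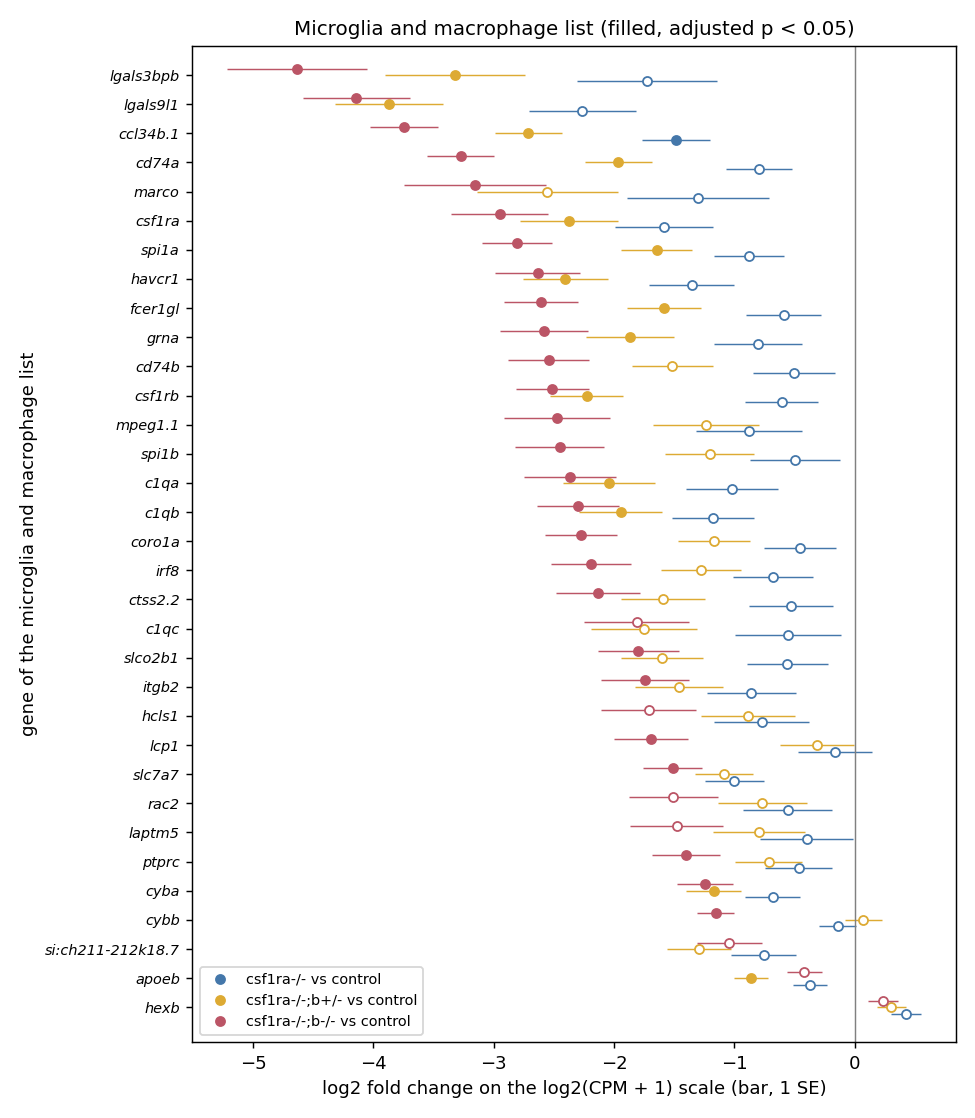
Log2 fold change of each of the 33 microglia and macrophage genes (y axis) against control on the log2(CPM + 1) scale (x axis), with bars of 1 SE, in single, csf1rb-heterozygous and double mutants. Filled points passed the test: 1, 14 and 26 genes. Most points of double mutants lie farthest to the left, and hexb lies right of 0 in all 3 mutants.

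Antigen presentation and interferon genes were lower in double mutants too. Of 13 antigen presentation genes (median -0.72), cd74a, mhc2dab (21.3 ± 13.9 to 1.46 ± 0.569 CPM, -3.06, adjusted p = 0.00251) and cd74b (88.8 ± 45.7 to 13.9 ± 4.83, -2.54, adjusted p = 0.00465) fell, and 8 fell adjusted over the list alone (adjusted p = 1.73e-08, and adjusted p = 0.481 with an estimated correlation). cd74a and cd74b are microglia genes too. Of 14 interferon response genes (median -1.38), stat1a fell (109.5 ± 15.5 to 62.9 ± 8.24, -0.79, adjusted p = 0.0309), and 11 fell adjusted over the list alone (adjusted p = 8.83e-09, and adjusted p = 0.481 with an estimated correlation). All 13 genes of the mitochondrial genome were lower, with a median of -0.29, 0 called over all genes and 3 fallen adjusted over the list alone (adjusted p = 0.00028, and adjusted p = 0.611 with an estimated correlation).

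Camera called 10 of the 34 lists in double mutants with the preset correlation and 0 with an estimated one. Lower medians were called for radial glia (-0.20, adjusted p = 0.0148), proliferation (-0.25, adjusted p = 0.017), heat shock and unfolded protein response (-0.22, adjusted p = 0.0239) and epidermis and muscle (-0.94, adjusted p = 0.0239). With an estimated correlation these had adjusted p = 0.652, 0.611, 0.611 and 0.481. Higher medians were called for the cytosolic ribosome (0.15, adjusted p = 0.0066) and immediate early genes (0.33, adjusted p = 0.0239), with adjusted p = 0.759 and 0.674 with an estimated correlation. Of the members of these 6 lists, only junbb of the immediate early genes passed, over all genes or adjusted over the list alone. Without control replicate 2 the epidermis and muscle median turned to 0.16 (adjusted p = 0.353), and adjusted p rose to 0.63 for radial glia, 0.34 for heat shock and 0.179 for immediate early genes. Without control replicate 1 it was 0.259 for proliferation. Without double mutant replicate 1 it was 0.0863 for heat shock and 0.0744 for epidermis and muscle, and without replicate 3 it was 0.0793 for immediate early genes. Without double mutant replicate 2 it was 0.108 for radial glia, 0.0698 for proliferation, 0.0646 for the ribosome and 0.272 for immediate early genes. Without all 3 mutant libraries numbered 2, which stood apart as given above, the immediate early median was 0.17 (adjusted p = 0.286).

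Single members of uncalled lists changed in double mutants. mbpa, myelin basic protein, fell from 7040 ± 826 to 4204 ± 501 CPM (-0.75, SE 0.13, adjusted p = 0.0222) while the oligodendrocyte and myelin list of 16 had a median of -0.10 (adjusted p = 0.265). This was not particular to double mutants, since mbpa lay below both control libraries (7624 and 6456 CPM) in the other mutants too. It stood at 4481, 4921 and 4592 CPM in single and at 4771, 4878 and 4418 in csf1rb-heterozygous mutants. ptprz1b rose from 129.7 ± 3.63 to 177 ± 12.6 (0.44, adjusted p = 0.0466) in the oligodendrocyte precursor list (median 0.046, adjusted p = 0.888). cldn5b, a tight junction gene, fell from 3.81 ± 0.281 to 1.16 ± 0.0736 (-1.15, adjusted p = 0.0236) in the endothelium list (-0.11, adjusted p = 0.104), vamp2 fell from 192.5 ± 9.07 to 125.8 ± 6.47 (-0.61, adjusted p = 0.0224) in the pan-neuronal list (-0.042, adjusted p = 0.0609), and grna, a microglia list member as well, fell by 2.59 (adjusted p = 0.00627) in the lysosome list (0.11, adjusted p = 0.104). pmvk, phosphomevalonate kinase, fell by 1.23 log2 units (adjusted p = 0.0367) in the cholesterol synthesis list (0.054, adjusted p = 0.82). gh1 fell in the pituitary hormone list of 3 tested genes (-0.68, adjusted p = 0.0781). Adjusted over the list alone, the same counts of 1 held in these 7 lists, except for 3 falls in the pan-neuronal and 1 further rise in the lysosome list. When control replicate 1 was left out, adjusted p was 0.143 for mbpa, 0.209 for ptprz1b, 0.201 for stat1a and 0.0786 for grna. Without control replicate 2, it was 0.144 for cldn5b, 0.146 for vamp2 and 0.281 for pmvk. The pan-neuronal (adjusted p = 0.000908), pituitary (0.0135) and lysosome (0.0235) lists were called without control replicate 1. So were the pan-neuronal list without double mutant replicate 2 (0.0143) and the endothelium list without replicate 3 (0.0038).

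The other lists gave no call in double mutants. Among immune and blood cells, medians were -0.31 for T and NK lymphocytes (adjusted p = 0.18), 1.2 for the 2 B lymphocyte genes (adjusted p = 0.18), 0.089 for neutrophils (adjusted p = 0.896), 6.71e-05 for erythrocytes (adjusted p = 0.265) and 0.047 for inflammation and acute phase genes (adjusted p = 0.888). Among vessel and barrier cells, they were 0.039 for mural cells and fibroblasts (adjusted p = 0.915) and 0.38 for lymphatic endothelium and scavenger cells (adjusted p = 0.16). Among neurons, they were -0.16 for neurogenesis and young neurons (adjusted p = 0.257), -0.17 for excitatory neurons (adjusted p = 0.0721), -0.14 for upper layer cortical homologs (adjusted p = 0.108), 0.11 for inhibitory neurons (adjusted p = 0.888), 0.029 for monoaminergic and cholinergic neurons (adjusted p = 0.888) and -0.0063 for hypothalamic neuropeptides (adjusted p = 0.888). The hypothalamic median turned to 0.12 and was called without control replicate 2 (adjusted p = 0.0475). The retina and pineal (-0.32, adjusted p = 0.321), pigment cell (-0.089, adjusted p = 0.76), circadian clock (0.039, adjusted p = 0.516) and csf1 receptor ligand (-0.10, adjusted p = 0.856) lists completed the set. Leaving out 1 library also brought calls for excitatory neurons (adjusted p = 0.0107 without control replicate 1 and 0.0327 without double mutant replicate 1), erythrocytes (0.00979 without control replicate 2), and retina and pineal (0.0215 without double mutant replicate 3). Adjusted over the list alone, 2 erythrocyte genes and 1 hypothalamic gene rose, and 1 gene each fell among upper layer homologs, inhibitory neurons, and retina and pineal.

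**Figure D3:**
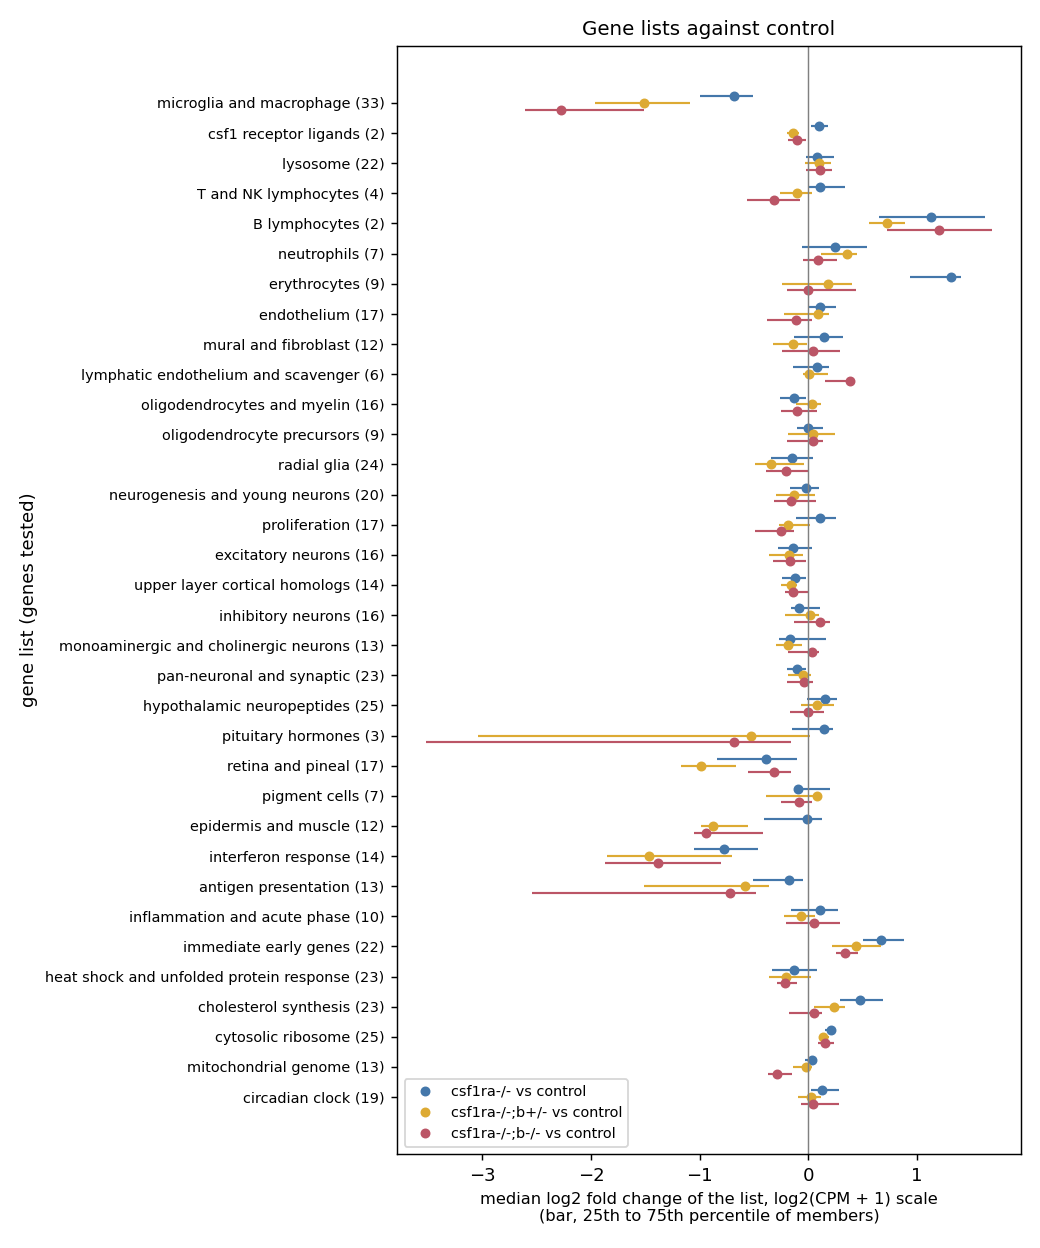
Median log2 fold change of each of the 34 gene lists (y axis, with the number of genes tested) in each mutant against control on the log2(CPM + 1) scale (x axis), with bars from the 25th to the 75th percentile of the members. The microglia and macrophage medians lie at -0.68, -1.51 and -2.28 in single, csf1rb-heterozygous and double mutants.

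In double mutants 60 genes rose and 132 fell, 142 of them by at least 1 log2 unit. gh1 fell from 94.3 ± 12.8 to 0.192 ± 0.332 CPM (-6.35, SE 0.715, adjusted p = 0.00201). Other large falls were those of lgals3bpb (87.7 ± 77.0 to 2.14 ± 1.74, -4.64, adjusted p = 0.00363), mrc1b (18.5 ± 10.5 to 0.704 ± 0.44, -3.44, adjusted p = 0.00502) and marco (19.3 ± 19.3 to 0.821 ± 0.925, -3.16, adjusted p = 0.029). junbb, an AP-1 transcription factor gene, rose from 62.4 ± 24.0 to 288.1 ± 50.0 (2.23, SE 0.44, adjusted p = 0.0369). Other large rises were in BX901918.1 (3.17), si:dkey-159n16.2 (2.85), CU856518.1 (2.45), CABZ01112732.1 (2.32), CT025651.1 (2.14), si:ch211-209j12.1 (1.93) and GUCY2C (1 of many) (1.89), with adjusted p from 0.00161 to 0.0421. Of the 27 named calls, 14 held in all 5 fits with a library left out, among them csf1rb, gh1, lgals3bpb, lgals9l1, ccl34b.1, cd74a, cd74b, mhc2dab and spi1a. Without control replicate 1, adjusted p was 0.22 for junbb, 0.159 for marco and 0.0598 for mrc1b. When control replicate 2 was left out, it was 0.156 for GUCY2C (1 of many) and 0.0623 for CU856518.1. The count of 192 was 82 and 123 without control replicates 1 and 2, and 74 and 111 without double mutant replicates 1 and 2. With control replicate 1 left out, 40 rose and 42 fell, and with control replicate 2 left out, 26 rose and 97 fell, so the excess of falls depended on a control library.

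Calls were denser on the chromosome that carries csf1rb and on 1 other chromosome, which carries neither receptor gene. In double mutants against control, 17 of 597 tested genes on the csf1rb chromosome were called against 138 of 14803 genes elsewhere (odds ratio 3.11, adjusted p = 0.00141, Fisher's exact test), and 22 of 784 on the other chromosome (odds ratio 3.14, adjusted p = 0.000319). With the microglia list left out, the odds ratio of the csf1rb chromosome was 2.36 (adjusted p = 0.223), and with DESeq2's calls it was 1.70 (adjusted p = 0.0535). On the chromosome of csf1ra, 8 of 557 genes were called (odds ratio 1.46, adjusted p = 0.757). In double mutants against control, 80.7% of called genes could be placed in the gene order. In the other 5 comparisons only 64.3% to 78.8% could be, which left the test void there.

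Some genes changed in all 3 mutants. Among the 11 that rose in each were BX901918.1, si:dkey-159n16.2, CT025651.1 and si:ch211-209j12.1, and among the 7 that fell were ccl34b.1 and, chosen after their values were seen, itgae.1 (an integrin gene) and tfr1b (a transferrin receptor gene, 120 CPM in control and 68.8, 71.5 and 78.0 in single, csf1rb-heterozygous and double mutants). In the fit without control replicate 1, adjusted p was 0.171 for itgae.1 in single mutants and 0.161 for tfr1b in double mutants. Without control replicate 2 it was 0.102 and 0.108 for tfr1b in single and csf1rb-heterozygous mutants. Single and csf1rb-heterozygous mutants shared 17 rises and 13 falls, single and double mutants 16 and 8, and csf1rb-heterozygous and double mutants 25 and 44. Independent lists of these sizes would share 0.12 to 0.53 genes. In 50 simulations of unchanged groups compared with the same 2 controls, at most 1 gene was shared, with means of 0 to 0.02. The simulated genes varied independently of each other, so only spread of single genes in the shared controls was covered. A shift of many genes together in a control library was not simulated. Such shifts occurred, since the microglia list median was 0.43 and -0.43 in the control libraries, set against their mean. The simulations therefore do not decide how many shared calls come from the shared controls. Part of the excess may still come from a difference of the controls from all mutants, such as one of family, which was not simulated. The 2 control libraries are too few to split.

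The comparison of csf1rb-heterozygous with single mutants sets apart groups that differ in csf1rb by their labels, with family differences not excluded. Microglia and macrophage genes were lower again (median -0.77, a ratio of 0.588), with csf1rb the only member called and 16 fallen adjusted over the list alone (adjusted p = 2e-19, and adjusted p = 0.297 with an estimated correlation). gh1 fell from 106.4 ± 28.8 to 2.39 ± 4.14 CPM (-5.70, SE 0.64, adjusted p = 0.00415). The erythrocyte list was lower (median -0.78, adjusted p = 5.06e-11, and adjusted p = 0.145 with an estimated correlation), where the alpha globins hbaa1 (197 ± 67.0 to 61.3 ± 18.3 CPM, -1.65, adjusted p = 0.0406) and hbaa2 (12.7 ± 6.35 to 1.59 ± 0.539, -2.31, adjusted p = 0.0298) fell and 5 members fell adjusted over the list alone. Of the antigen presentation list (-0.40, adjusted p = 1.02e-08, and adjusted p = 0.282 with an estimated correlation), mhc2dab fell, with 290 reads in single mutants and 3 in csf1rb-heterozygous mutants (a ratio of 107 in CPM, 95% counting interval 36.4 to 524), and 4 members fell adjusted over the list alone. Cholesterol synthesis was lower (-0.36, 0 called and 4 fallen adjusted over the list alone, adjusted p = 1.14e-09, and adjusted p = 0.145 with an estimated correlation).

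Camera called 11 lists between csf1rb-heterozygous and single mutants with the preset correlation and 0 with an estimated one. The other 7 lists held 0 called members, and 1 epidermis and muscle gene fell adjusted over the list alone. Medians were -0.23 for proliferation (adjusted p = 0.000568, and adjusted p = 0.417 with an estimated correlation) and -0.61 for epidermis and muscle (adjusted p = 0.00097, and adjusted p = 0.248 with an estimated correlation). They were -0.57 for interferon response (adjusted p = 0.00326), -0.15 for radial glia (adjusted p = 0.00787) and -0.24 for immediate early genes (adjusted p = 0.0164), each with adjusted p = 0.691 with an estimated correlation. Mural cells and fibroblasts were lower (-0.33, adjusted p = 0.0069, and adjusted p = 0.462 with an estimated correlation) and oligodendrocytes and myelin higher (0.10, adjusted p = 0.0102, and adjusted p = 0.355 with an estimated correlation). The circadian clock list (-0.079) was not called without the replicate number as a block (adjusted p = 0.149) and was called with it (adjusted p = 0.0249). Without single mutant replicate 3 the interferon list lost its call (adjusted p = 0.702), as without csf1rb-heterozygous replicate 3 (0.0908). Radial glia lost theirs without single mutant replicate 1 (0.514) or csf1rb-heterozygous replicate 3 (0.368), mural cells without replicate 2 of either group (0.0782 and 0.178), and myelin without single mutant replicate 2 (0.0939) or csf1rb-heterozygous replicate 1 (0.1). Immediate early genes lost theirs without single mutant replicates 1 and 2 (0.467 and 0.156) and without csf1rb-heterozygous replicates 1 and 3 (0.0637 and 0.405). Leaving out 1 library brought calls too. The ribosome list was called without single mutant replicate 1 (-0.18, adjusted p = 9.41e-09) or csf1rb-heterozygous replicate 2 (-0.15, adjusted p = 1.97e-06), and retina and pineal without single mutant replicate 1 (-1.26, adjusted p = 6.97e-08) or csf1rb-heterozygous replicates 1 or 2 (-0.76 and -0.69, adjusted p = 0.0249 and 0.00999). So were pituitary hormones without single mutant replicate 3 (adjusted p = 0.0193) or csf1rb-heterozygous replicates 1 or 3 (0.0261 and 0.0449), and heat shock without single mutant replicate 3 (0.0251) or csf1rb-heterozygous replicate 2 (0.0339). T and NK lymphocytes followed without single mutant replicate 1 (0.0291), neurogenesis and the mitochondrial genome without csf1rb-heterozygous replicate 2 (0.0339 for both) and the circadian clock without csf1rb-heterozygous replicate 3 (0.0142). Without the libraries numbered 2 of both groups, the mural list had a median of -0.09 (adjusted p = 0.28).

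Between these groups 12 genes rose and 19 fell. si:ch211-181d7.3 (6.19 ± 3.00 to 63.7 ± 12.3 CPM, 3.25), BX322555.3 (2.12), si:ch211-272b8.6 (2.09) and paqr3b (1.85), which were lower in single mutants than in control, were higher here (adjusted p from 0.00447 to 0.0298), as was AL928808.1 with 1 read against 248 (a ratio of 223 in CPM, 95% counting interval 39.7 to 8850). si:dkey-23k10.5 (-2.32) and si:dkey-48g21.7 (-2.00) fell (adjusted p = 0.038 for both). Of the 12 named calls, 5 held in all 6 fits with a library left out: gh1, mhc2dab, si:ch211-181d7.3, AL928808.1 and si:ch211-272b8.6. Without csf1rb-heterozygous replicate 1, adjusted p was 0.211 for hbaa1, 0.165 for hbaa2 and 0.12 for paqr3b. Without single mutant replicate 3 it was 0.108 for BX322555.3 and 0.173 for both si:dkey-23k10.5 and si:dkey-48g21.7. The count of 31 fell to between 9 and 16 in each of those 6 fits: 12, 14 and 13 without single mutants 1 to 3, and 9, 16 and 11 without csf1rb-heterozygous mutants 1 to 3.

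The comparison of double with single mutants asks how brains with mutated csf1ra differ when csf1rb is mutated too. Microglia and macrophage genes had a median of -1.37 (a ratio of 0.387), and 14 of 33 members fell (adjusted p = 3.19e-35, and adjusted p = 0.215 with an estimated correlation). cd74a fell from 150.1 ± 56.4 to 25.2 ± 5.06 CPM (-2.48, adjusted p = 0.00102), ccl34b.1 from 8.18 ± 2.19 to 0.932 ± 0.562 (-2.26, adjusted p = 0.00211), spi1a from 4.34 ± 1.21 to 0.405 ± 0.291 (-1.92, adjusted p = 0.0058) and cybb, the catalytic subunit of the phagocyte NADPH oxidase, from 23.4 ± 2.32 to 11.1 ± 2.00 (-1.01, adjusted p = 0.0058). Cholesterol synthesis had a median of -0.52 (adjusted p = 6.07e-17, and adjusted p = 0.0566 with an estimated correlation), with 6 of 23 members fallen, among them msmo1 (55.6 ± 8.63 to 27.3 ± 0.31 CPM, -0.99, adjusted p = 0.0064), cyp51 (63.4 ± 6.69 to 34.2 ± 2.57, -0.87, adjusted p = 0.00648), lss (18.4 ± 2.08 to 9.28 ± 1.38, -0.92, adjusted p = 0.0102) and hmgcs1 (99.2 ± 13.1 to 48.2 ± 6.47, -1.03, adjusted p = 0.0159). In the control libraries msmo1 stood at 35.2 and 37.1 CPM and cyp51 at 39.5 and 36.95. lss stood there at 7.10 and 8.02 CPM and hmgcs1 at 44.1 and 44.6. All these control values lay below those of the single mutant libraries. Against control, the cholesterol synthesis median of double mutants was 0.054 and was not called. gh1 fell by 6.49 (SE 0.64, adjusted p = 0.000966).

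Camera called 12 lists between double and single mutants with the preset correlation, all lower, and 0 with an estimated one. The microglia list had 30 members fallen adjusted over the list alone, and cholesterol synthesis 13. In the antigen presentation list (-0.52, adjusted p = 1.49e-08) cd74a, cd74b (-2.04, adjusted p = 0.00858) and mhc2dab (-1.76, adjusted p = 0.0269) fell, and 5 members fell adjusted over the list alone. In the erythrocyte list (-0.78, adjusted p = 4.95e-07) hbaa1 fell (197 ± 67.0 to 63.2 ± 15.8 CPM, -1.59, adjusted p = 0.0173), and 7 members fell adjusted over the list alone. hbaa1 stood at 74.1 and 67.6 CPM in the control libraries, below all single mutant libraries. T and NK lymphocyte (4 genes tested, -0.68, adjusted p = 0.00539, 3 fallen adjusted over the list alone), epidermis and muscle (-0.57, adjusted p = 0.00539) and pituitary hormone genes (-0.24, adjusted p = 0.0401) were lower. Only 3 pituitary hormone genes were tested, gh1, pomca and prl2, and gh1 alone was called. All 5 lists had adjusted p = 0.215 with an estimated correlation. Proliferation (-0.39, adjusted p = 2.63e-05), mitochondrial genome (-0.29, adjusted p = 1.67e-05), endothelium (-0.27, adjusted p = 0.00193), immediate early (-0.37, adjusted p = 0.00368) and interferon response genes (-0.48, adjusted p = 0.00376) were lower as well, with adjusted p = 0.302, 0.439, 0.617, 0.672 and 0.78 with an estimated correlation. Of these 5 lists only egr3, a transcription factor gene induced by activity, was called (114 ± 7.06 to 65.7 ± 9.91 CPM, -0.80, adjusted p = 0.0205). egr3 stood at 56.6 and 76.7 CPM in the control libraries, also below all single mutant libraries. Adjusted over the list alone, 2 proliferation, 1 mitochondrial, 2 endothelium and 1 immediate early gene fell and 1 immediate early gene rose. Without single mutant replicate 1, adjusted p was 0.123 for immediate early genes, 0.0975 for epidermis and muscle and 0.0647 for pituitary hormones. Without double mutant replicate 1 it was 0.182 for immediate early genes and 0.157 for pituitary hormones. The pituitary call was lost without single mutant replicate 2 (0.193), the interferon call without single mutant replicate 3 (0.44) and the endothelium call without double mutant replicate 2 (0.397). The ribosome list was called without single mutant replicate 1 (-0.18, adjusted p = 8.79e-06), retina and pineal lower without single mutant replicate 1 (-0.70, adjusted p = 0.0278) and higher without double mutant replicate 2 (0.98, adjusted p = 0.00471), and lymphatic endothelium and scavenger cells without single mutant replicate 3 (0.41, adjusted p = 0.0462) or double mutant replicate 2 (0.31, adjusted p = 0.0199).

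Between double and single mutants 54 genes rose and 102 fell, 122 of them by at least 1 log2 unit. gstm.2, a glutathione transferase gene, fell from 46.6 ± 1.36 to 2.69 ± 0.397 CPM (-3.70, SE 0.121, adjusted p = 4.41e-08). spint2, a protease inhibitor gene, fell from 21.2 ± 3.01 to 1.05 ± 0.363 (-3.44, adjusted p = 0.0109) and loxl2b, a lysyl oxidase gene, from 110.6 ± 23.1 to 12.2 ± 13.3 (-3.61, adjusted p = 0.0201). CU019657.1 fell likewise (-3.73, adjusted p = 0.0205), and grna by 1.78 (adjusted p = 0.0263). The control libraries held gstm.2 at 16.5 and 19.8 CPM, below the single mutants. They differed widely from each other in spint2 (11.8 and 0.849 CPM), loxl2b (99.6 and 28.2) and CU019657.1 (15.8 and 0.694). The largest rises were again in genes that had been lower in single mutants than in control: si:ch211-181d7.3 (3.37), si:ch211-272b8.6 (2.77), BX322555.3 (2.69), paqr3b (2.21) and AL928808.1 (1 against 277 reads, a ratio of 247 in CPM, 95% counting interval 43.9 to 9780), with adjusted p from 0.000418 to 0.00503. Of the 24 named calls, 15 held in all 6 fits with a library left out, gstm.2, gh1, cd74a, ccl34b.1, spi1a, cybb, csf1rb, msmo1 and cyp51 among them. Without single mutant replicate 3, adjusted p was 0.0621 for lss, 0.0831 for hmgcs1, 0.0863 for hbaa1, 0.125 for mhc2dab, 0.121 for grna, 0.0941 for loxl2b and 0.097 for CU019657.1. Without double mutant replicate 2 it was 0.0526 for spint2, and without single mutant replicate 1 it was 0.09 for egr3. The count of 156 was 98 and 66 without single mutant replicates 1 and 3, and 78 and 79 without double mutant replicates 1 and 2. Members of the microglia list that fell numbered 8 without single mutant replicate 1 or 3 and without double mutant replicate 1 or 2.

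The comparison of double with csf1rb-heterozygous mutants asks how brains with both csf1rb copies mutated differ from those with 1. cybb fell from 27.2 ± 1.91 to 11.1 ± 2.00 CPM (-1.23, SE 0.137, adjusted p = 0.0044), the only microglia gene called, while the list of 33 had a median of -0.69 (a ratio of 0.621) with 12 members fallen and 1 risen adjusted over the list alone (adjusted p = 5.18e-17, and adjusted p = 0.887 with an estimated correlation). cybb stood at 25.8 ± 0.609 CPM in control and 23.4 ± 2.32 in single mutants. gstm.2 fell from 20.8 ± 0.398 to 2.69 ± 0.397 (-2.57, SE 0.121, adjusted p = 2.67e-06). dpyda.3 rose from 3.91 ± 1.08 to 16.4 ± 2.76 (1.83, SE 0.21, adjusted p = 0.0044) and col28a1b, a collagen gene, from 1.25 ± 0.385 to 6.12 ± 1.48 (1.66, adjusted p = 0.0429).

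Between double and csf1rb-heterozygous mutants 6 genes rose and 8 fell. si:ch73-59c19.1 (2.01, adjusted p = 0.0159) and si:rp71-77l1.1 (1.74, adjusted p = 0.0044) rose, and si:dkey-199f5.6 (-2.55, adjusted p = 0.00158), si:dkey-23a13.11 (-2.11, adjusted p = 0.00596), si:ch73-233k15.2 (-1.44, adjusted p = 0.0336) and si:ch211-93g21.1 (-1.40, adjusted p = 0.0395) fell. Camera called 5 lists with the preset correlation and 0 with an estimated one. These were the microglia list (adjusted p = 5.18e-17), cholesterol synthesis (-0.27, adjusted p = 8.37e-08), the mitochondrial genome (-0.19, adjusted p = 1.62e-05), endothelium (-0.16, adjusted p = 0.0297) and, higher, retina and pineal (0.64, adjusted p = 0.0418). With an estimated correlation their adjusted p = 0.887, 0.431, 0.887, 0.887 and 0.933. Of the last 4 lists 0 members were called over all genes, and 1 mitochondrial gene fell adjusted over the list alone. The endothelium call was lost without csf1rb-heterozygous replicates 1 or 3 (adjusted p = 0.0779 and 0.147) or double mutant replicate 2 (0.944). The retina and pineal call was lost without csf1rb-heterozygous replicate 3 (0.766) or double mutant replicates 1 or 3 (0.247 and 0.874). Leaving out 1 library brought calls for mural cells and fibroblasts (0.26, 0.22 and 0.29, adjusted p = 0.00736, 0.00612 and 0.0108 without csf1rb-heterozygous replicate 1 and double mutant replicates 1 and 2), lymphatic endothelium and scavenger cells (0.47 and 0.42, adjusted p = 0.00387 and 0.00559 without csf1rb-heterozygous replicate 3 and double mutant replicate 2) and radial glia (0.09 and 0.14, adjusted p = 0.0373 and 0.0157 without csf1rb-heterozygous replicate 1 and double mutant replicate 2). Ribosome genes were lower without csf1rb-heterozygous replicate 1 (-0.09, adjusted p = 0.012) and higher without its replicate 2 (0.11, adjusted p = 0.000845). Further calls were those of proliferation without replicate 1 of either group (adjusted p = 0.0373 and 0.0364), immediate early genes without csf1rb-heterozygous replicate 3 (0.0477) or double mutant replicate 2 (0.0108) and myelin without double mutant replicate 3 (0.00649). Of the 10 named calls, cybb, gstm.2, dpyda.3, si:rp71-77l1.1 and si:dkey-199f5.6 held in all 6 fits with a library left out. Without csf1rb-heterozygous replicate 1, adjusted p was 0.0781 for si:ch73-59c19.1 and 0.0542 for si:dkey-23a13.11. Without replicate 2 of that group it was 0.179 for col28a1b, 0.167 for si:ch73-233k15.2 and 0.168 for si:ch211-93g21.1. The count of 14 was 8 and 9 without csf1rb-heterozygous replicates 1 and 2, and 36 without double mutant replicate 3.

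**Figure D4:**
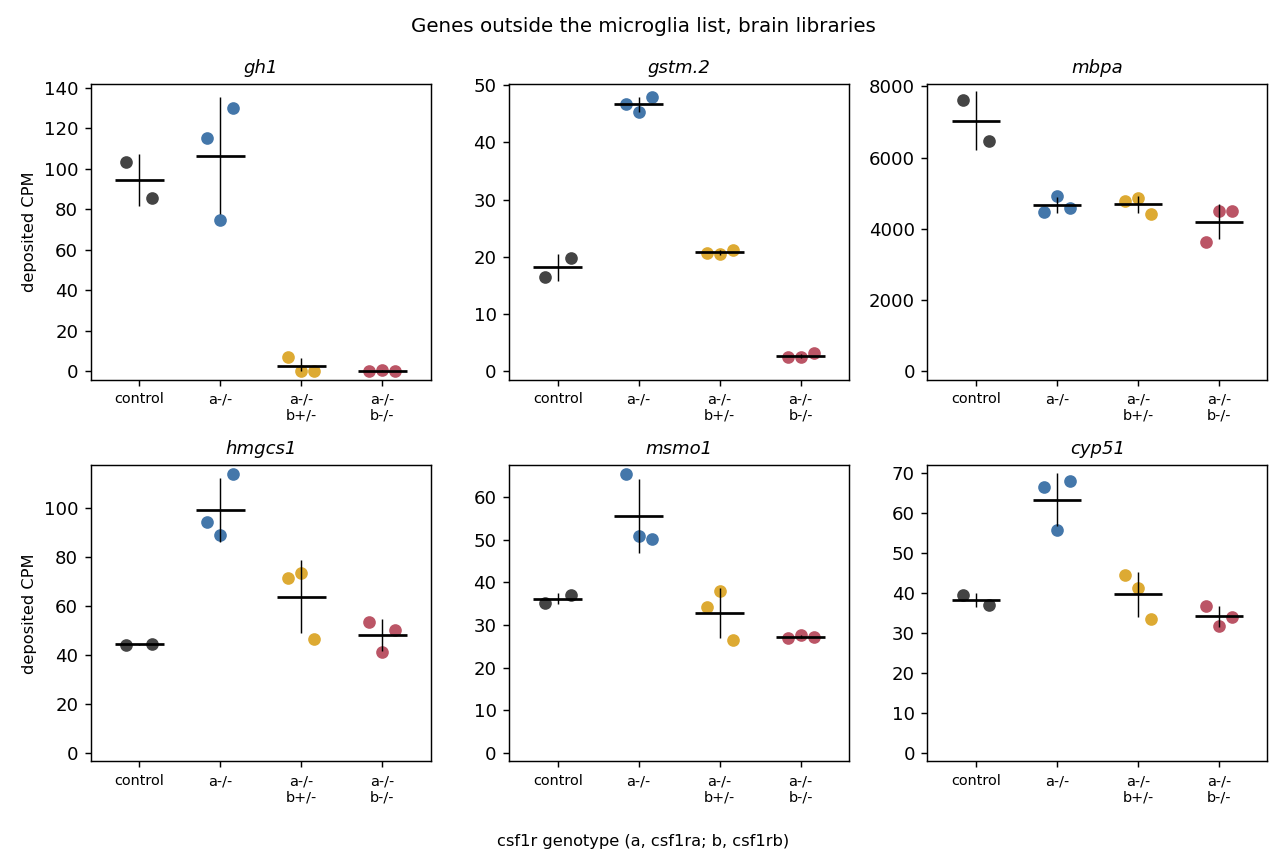
Level of 6 genes outside the receptors in each library (y axis, CPM), by genotype (x axis), with the mean and SD of each group. gh1 lies at 74.4 to 130 CPM in control and single mutant libraries and at 0 to 7.17 CPM in the 6 libraries with a csf1rb mutation.

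The authors' deposited table called 75, 76 and 204 genes in single, csf1rb-heterozygous and double mutants against control, of which 67, 76 and 181 were also called here. Between mutants it called 26 genes for csf1rb-heterozygous against single, 156 for double against single and 17 for double against csf1rb-heterozygous mutants, of which 23, 146 and 13 were also called here.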

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

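The alternatives chosen only after the data were seen were edgeR's quasi-likelihood test, the block by description number, the minimum mean log2 CPM of 1, the fits without the mutant libraries numbered 2, the microglia list without csf1ra and csf1rb, and the chromosome test with the microglia list left out. Comparisons are given in the order single, csf1rb-heterozygous and double mutants against control, then csf1rb-heterozygous against single, double against single and double against csf1rb-heterozygous mutants. Median-of-ratios scaling changed no call of the 144 gene results and 198 list results compared. The filters on low values removed no gene.

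The numbers of called genes depended on the test. DESeq2 called 285, 528, 621, 126, 430 and 98 genes. Limma-voom called 47 in single and 57 in csf1rb-heterozygous mutants against control and 7 in csf1rb-heterozygous against single mutants. A pseudocount of 0.25 gave 72 for csf1rb-heterozygous mutants, and a fit of only the 2 groups compared gave 116 for double mutants, both against control. With the number in the title as a block, 322 genes were called in double mutants against control, 294 in double against single and 24 in double against csf1rb-heterozygous mutants. With the number in the description as a block, 136 were called in single mutants against control and 367 in double against single mutants. Among genes with a mean log2 CPM of at least 1, 65 were called in csf1rb-heterozygous and 126 in double mutants against control, where fewer genes were tested. Without the mutant libraries numbered 2, which leaves fewer samples, 42 were called in single mutants against control, 8 in csf1rb-heterozygous against single, 79 in double against single and 5 in double against csf1rb-heterozygous mutants. For the other settings the cause was not tested. Leaving out 1 library gave 29 to 65, 48 to 62, 74 to 133, 9 to 16, 66 to 151 and 8 to 36 genes.

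The microglia and macrophage list had a negative median under each setting run. Leaving out 1 library gave medians of -1.14 to -0.288, -1.95 to -1, -2.72 to -1.63, -0.906 to -0.593, -1.60 to -1.26 and -0.888 to -0.466, and the call with the preset correlation was not lost. The other settings gave -0.835 to -0.518, -1.69 to -1.04, -2.95 to -1.33, -1.04 to -0.437, -2.11 to -0.859 and -1.08 to -0.331. With an estimated correlation the medians of -0.681, -1.51, -2.28, -0.766, -1.37 and -0.687 stayed as they were but were not called (adjusted p = 0.645, 0.5, 0.268, 0.297, 0.215 and 0.887). That setting estimates how far the members vary together, which widens the error of a list whose genes share a cell type. It ended the 51 calls among the 198 other list results.

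Of the 144 gene results, limma-voom ended 41 calls, edgeR 17, DESeq2 3 and the block by title number 3, while DESeq2 brought 1. Of the 198 list results, edgeR ended 2 calls and brought 5, DESeq2 5 and 4, limma-voom 5 and 3, and the block 3 and 5. In csf1rb-heterozygous against single mutants, the paired comparison, the block brought the circadian clock call (adjusted p = 0.0249) and changed no other call among the named genes and lists. Over all genes, 31 were called without the block and 35 with it, with 29 shared. Some medians turned sign when 1 library was left out. Epidermis and muscle ranged from -1.45 to 0.224 in csf1rb-heterozygous and from -1.49 to 0.156 in double mutants, and hypothalamic neuropeptides from -0.161 to 0.117 in double mutants, lowest without control replicate 1 and highest without control replicate 2. Retina and pineal ranged from -0.701 (without single mutant replicate 1) to 0.976 (without double mutant replicate 2) in double against single mutants. Pituitary hormones, with 3 genes tested, ranged from -0.246 (without single mutant replicate 3) to 0.0257 (without csf1rb-heterozygous replicate 1) in csf1rb-heterozygous against single mutants. The ribosome ranged from -0.0924 to 0.109 in double against csf1rb-heterozygous mutants, without csf1rb-heterozygous replicates 1 and 2. For these the cause was not tested. The odds ratio of the csf1rb chromosome fell from 3.11 to 1.70 with DESeq2's calls (adjusted p = 0.0535), for which the cause was not tested, and to 2.36 with the microglia list left out (adjusted p = 0.223), where 11 of 590 tested genes were called instead of 17 of 597.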

Other observations

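The genes in the next 2 paragraphs were chosen after their values were seen, and of the tests that follow, only the splits of the libraries and the test of neighbouring genes were chosen before their results were seen. They are reported one by one, and no group of them was tested. In double mutants against control, the phosphatase genes ptpn6 (10.4 ± 5.04 to 1.45 ± 0.856 CPM, -2.21, adjusted p = 0.0133) and inpp5d (10.98 ± 2.87 to 2.18 ± 0.266, -1.90, adjusted p = 0.00465), the chemoattractant receptor genes cmklr1 (-2.15, adjusted p = 0.00627) and cxcr3.2 (3.90 ± 0.714 to 0.128 ± 0.167, -2.12, adjusted p = 0.00251), and pfn1, a profilin gene (65.4 ± 36.0 to 15.0 ± 3.02, -1.96, adjusted p = 0.0098), fell. Only cxcr3.2 of these 5 was called in each fit with a library left out. Adjusted p was 0.119, 0.0534 and 0.0577 for ptpn6, inpp5d and pfn1 without control replicate 1 and 0.0504 for cmklr1 without control replicate 2.

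pcdh1gc5, a protocadherin gene of the adhesion molecules of neurons, stood at 67.9 ± 2.66 CPM in control, 41.0 ± 7.91 in single, 26.1 ± 1.99 in csf1rb-heterozygous and 15.0 ± 5.94 in double mutants, and fell in double mutants against control (-2.16, adjusted p = 0.00196, and 0.0262 without control replicate 1). Another, pcdh1g30, was not called in double mutants and fell in single mutants (51.2 ± 0.238 to 18.7 ± 3.56, -1.42, adjusted p = 0.00382, and 0.047 without control replicate 2) and in csf1rb-heterozygous mutants against control (-1.25, adjusted p = 0.00901, and 0.058 without control replicate 2). These genes form a cluster of close copies, so their levels are uncertain with reads of 50 nucleotides. alox5b.3, a lipoxygenase gene, stood at 0.28 ± 0.0687 CPM in control, 15.2 ± 7.70 in single and 0.113 ± 0.0378 in csf1rb-heterozygous mutants, and rose in single mutants against control (3.52, adjusted p = 0.00159). Its fall in csf1rb-heterozygous against single mutants (-3.72, adjusted p = 0.00213) held in each of 6 fits with a library left out.

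Other splits of the 6 libraries of 2 mutants were counted. For csf1rb-heterozygous against single mutants the real split gave 31 genes and the highest of the other 9 gave 1. For double against single mutants these were 156 and 0, and for double against csf1rb-heterozygous mutants 14 and 0. In each case 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

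gh1 stood at 74.4 to 130 CPM in the 5 control and single mutant libraries and at 0 to 7.17 in the 6 others, 4 of them at 0. Pituitary glands left on the brains of the first groups would bring other pituitary transcripts along. In the csf1rb mutants the log2 difference was 0.31 for pomca (95% confidence interval -0.121 to 0.741) and -0.385 for prl2 (-0.944 to 0.174), the other hormone genes tested. pomca is also made in the hypothalamus, and both were low (3.42 to 7.78 and 1.08 to 6.33 CPM), so glands, whole or in part, stay open. A library swapped between these sides would lie at the level of the other side, while the lowest of the 5 lay 10.4 times above the highest of the 6. That follows from the pattern as first seen and is no separate test. Swaps within a side would leave gh1 unchanged and cannot be seen. A difference of genotype or family stays open and was not tested. Of 16536 genes, only gh1 and lgals3bpb had no overlap between these sides and a log2 difference of -3 or lower.

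The 3 mutant libraries numbered 2 stood apart on the first principal component, as given above, and no control bears that number in its description. Libraries with the same number deviated together in single and csf1rb-heterozygous mutants but did not pair throughout in the other comparisons. Of 16536 genes, 1184 differed between the numbers in the sample descriptions. Of 19 circadian clock genes 8 did, among them per2, per3, nr1d1 and nr1d2a (42.1% against 7.12% of other genes, p = 2.5e-05, Fisher's exact test), so the time of day of sampling may have differed between the numbers. In each mutant, nr1d1, nr1d2a, nr1d4a, per2 and ciarta at number 2 lay between numbers 1 and 3, while clocka and tefb were lowest at number 2. The shift of the former genes therefore does not account for the libraries numbered 2 standing apart. Of 22 immediate early genes 10 differed between the numbers (45.5%, p = 9.95e-07, Fisher's exact test), so handling before freezing may have differed as well, and the tests do not separate these 2 explanations. Sequencing depth as the source of the difference was argued against, since the reads of 0 of the 3 mutant libraries numbered 2 lay outside the range of the other libraries. No biological explanation was tested.

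Of 354 genes called in any comparison, 327 were not on the microglia list, and 31.6% of called genes had clone-type names against 15.0% of all genes. Haplotypes that differ between families of fish could bring calls in neighbouring genes. Of the 327 genes, 45 had another called gene, whose name starts differently, within 5 places. The median was 26 in 10000 random draws (14 to 39, permutation p = 0.0044). Among the 257 that could be placed (78.6% against 93.1% of all genes), calls thus lay together more often than drawn genes. The cause stays undecided. Within 100 places of csf1ra or csf1rb, 1 of 196 genes was called in double mutants (odds ratio 0.603, 95% confidence interval 0.0151 to 3.46), an interval too wide to decide on haplotypes linked to the mutations. Effects of the mutations stay open beside both.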
